A study of Mus musculus with 18 samples.

How the data were processed

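RNA was measured in the cochlea of 4-week-old mice. Per the labels, the cochlea was divided into base, middle and apex, and each region was taken from control mice and from mice with a conditional knock-out (cKO) of Fst, the gene of follistatin, a secreted protein that binds activins. The labels describe 1 RNA pool per region and genotype and 3 technical libraries made from each pool, which gives 6 groups and 18 libraries. Libraries were made with a TruSeq RNA v2 kit and Ribo-Zero, per the labels.

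The submitters' processing notes name STAR 2.5.2b and Cuffdiff 2.2.1 and the genome build GRCm38/mm10, without saying which step each tool did. The table deposited by the authors holds 46583 genes. Its count columns hold estimated counts per gene and library made by the authors, as deposited, by a step the notes do not name, and are not scaled to a common total. The headers say only counts, and the columns were taken for expected counts because part of the values is not whole. The table also holds values in fpkm (FPKM) computed by the authors per library, and the authors' mean FPKM per group. Between 89.2% and 89.9% of the expected counts of a library were whole numbers within a tolerance of 1e-06, and all were rounded before the count models. No row lacked a gene name, 126 symbols stood on more than 1 row, and genes were kept apart by Ensembl identifier. Positions came from GENCODE release M21 on GRCm38/mm10, in which 46074 of the genes were found. Every library column was used, and the authors' group means served only as a check of the file.

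Library totals ran from 24446760 to 33732726 counts, with a median of 28749804. A library held 21781 to 22726 genes with at least 1 count, and its 10 most abundant genes took 7.98% to 11.3% of the counts. A floor of 3 counts, the limit that a count of 0 allows, corresponds to 0.0889 to 0.123 CPM, counts scaled to the total of a library. Reads carry no molecular identifiers, so intervals and floors cover counting error only. Libraries of the same pool were compared by a chi-square over genes with at least 20 counts, which came to 1.19 to 1.59 per degree of freedom. The pair farthest apart held control base replicate 3, the library with the lowest total. They were not merged, because merging leaves 1 value per group and no spread within a group.

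Counts were modelled with edgeR 4.0.16 (R 4.3.3): filterByExpr left 17901 genes, TMM factors ran from 0.977 to 1.03, and quasi-likelihood F tests (two-sided) used 1 shared design of 6 groups with 12 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05 with an absolute log2 fold change of at least 1. The fold threshold was set because technical libraries of 1 pool vary so little: the common biological coefficient of variation of edgeR was 0.00988 among libraries, which here is technical spread. In the fit on the 6 summed pools it was 0.116. That value is what region and genotype leave unexplained, and no group holds a second pool to measure spread between like pools. Every p-value of the fits on libraries carries the spread between libraries, not between animals, and each group holds n = 1 pool. An error after a log2 change is the standard error of the fit with n = 3 libraries per group. The error after a CPM value is the SD of the 3 libraries. A genotype effect over the regions was also tested on the 6 summed pools with region as a factor, with 2 residual degrees of freedom. The 3 regions of a genotype may come from the same animals, so that test does not measure the spread between animals either.

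The comparisons were cKO against control in each region, the regions of the control against each other, apex against base in the cKO, and the difference between the apex-base changes of cKO and control. The last is an interaction contrast. For genes with 0 counts in all libraries of the lower group, a lower bound of the fold was computed with 3 counts over that group. With 1 to 3 counts in the lower group, the ratio of the summed counts is given with its exact (Clopper-Pearson) 95% interval, because the fitted fold change then depends on the prior count.

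Gene lists numbering 32, with 483 members, were written for cochlear cell types, pathways, neighbouring tissues and states of the sample. Of their members 482 were found, 5 by an older symbol, and some genes stand on more than 1 list. Lists were tested with limma 3.58.1 (camera on voom values, preset correlation 0.01) in 6 comparisons, giving 192 tests adjusted together. The tests were repeated with an estimated correlation and with fry, which tests whether the genes of a list move on balance 1 way and compares them with no other genes. Camera at the preset correlation called 106 tests, of which 95 held with an estimated correlation, and fry called 181. A list's median was also taken with members at 0 counts in a group set at their bound. Genes graded between control middle and control base were followed into the apex comparison, with which they share no library, with p-values adjusted over the 2 lists.

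The genes named in the text were picked by rule. Fst and the sex-chromosome transcripts are always given for the 3 genotype comparisons. For each of the 3 genotype comparisons, control apex against base and the gradient difference, the rule takes the 10 called genes with the largest increase and the 10 with the largest decrease. The higher group needs a mean of at least 2 CPM and the libraries of both groups must not overlap (for the gradient difference, only the CPM rule). Predicted genes, clones, histone and small RNA genes were left out. From each list up to 4 members come by lowest adjusted p, and any other gene named was picked after its values were seen. Some genes that the rule or a list picked are not given in the text. Groups, comparisons, tests, lists, naming rule and a first set of alternatives were fixed before the data were examined.

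The alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, only the groups of a contrast, no fold threshold, an absolute log2 fold change of at least 2, limma-trend on log2 FPKM with 0.1 or 1 added, library sizes without blood and mitochondrial lists, the replicate number as a block, and leaving out each library. Counting only genes with a mean of at least 5 CPM and dropping the 133 members of other-tissue and sex-chromosome lists were added after seeing the data, as was DESeq2 on the summed pools with the genes that pass the filter. In the 6 libraries of each comparison, other splits into groups of the same size were fitted in the same way.

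The workflow was tested on simulated data with the size and spread of the apex comparison (17584 genes). Of 66 genes changed 2.5-fold, 98.5% were called, and of 64 changed 4-fold, 98.4%. Of 67 genes changed 1.5-fold, 0% passed the fold threshold and 85.1% were called without it. Of 17387 unchanged genes 0 were called, or 7 without the fold threshold. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.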

Results

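The data are expected counts per gene from bulk RNA sequencing of the cochlea of 4-week-old mice. There were 6 groups, base, middle and apex of control and of Fst cKO mice, with 3 technical libraries of 1 RNA pool each. Low-frequency sound is received in the apex and high-frequency sound in the base, and the series asks how follistatin and the hedgehog pathway relate to the identity of the apex. Library totals ran from 24446760 to 33732726 counts. With 1 pool per group, a difference between groups is a difference between pools, whatever its p-value.

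Fst itself (ENSMUSG00000021765, minus strand, chromosome 13, 114452290 to 114458951, GRCm38/mm10, protein coding) was graded along the control cochlea. Its mean level was 2.22 ± 0.214 CPM in control base, 6.4 ± 0.578 in control middle and 23.8 ± 0.86 in control apex. In the cKO it was 1.89 ± 0.124 CPM in base, 2.97 ± 0.347 in middle and 9.74 ± 0.384 in apex. The control apex libraries held 671, 722 and 712 Fst counts and the cKO apex libraries 260, 258 and 278. In the middle, control libraries held 197, 191 and 166 counts against 91, 97 and 114 in the cKO. In the base, they held 64, 63 and 59 against 51, 49 and 45. Fst was lower in the cKO by a log2 change of -1.29 ± 0.063 in the apex (edgeR, adjusted p = 1.51e-18) and -1.1 ± 0.099 in the middle (adjusted p = 2.38e-11). The base change of -0.22 ± 0.15 did not pass (adjusted p = 0.308). A conditional allele may leave part of the transcript, so a gene-level count is only a partial check of the genotype labels.

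**Figure D1:**
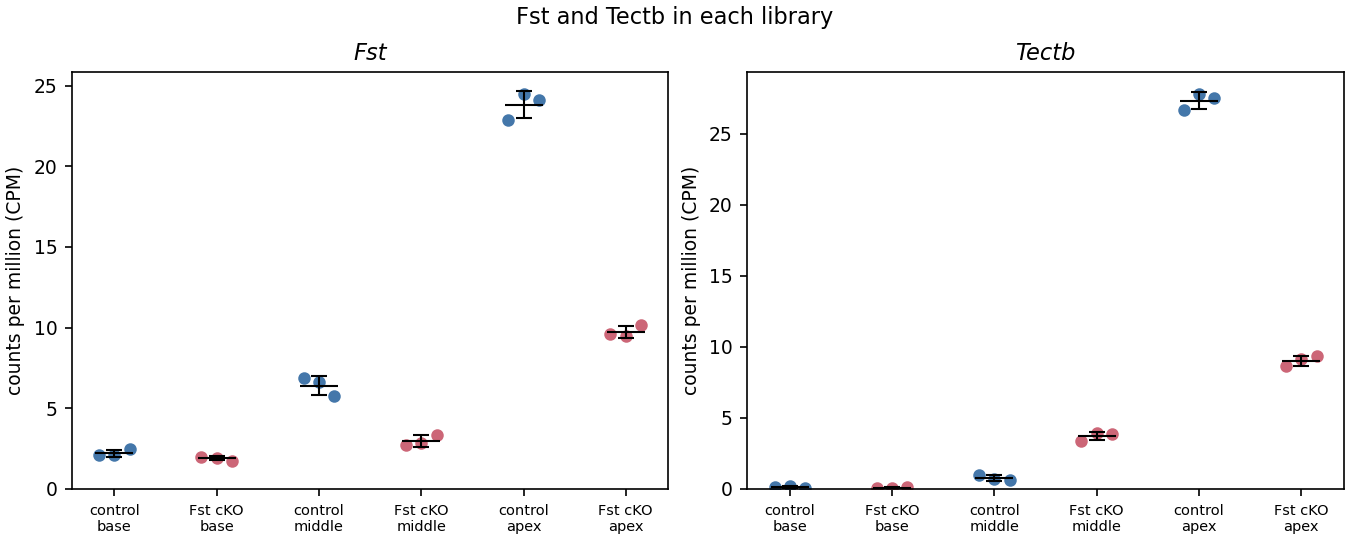
Fst and Tectb in CPM in each of the 18 libraries, by region and genotype, with the mean and SD of the 3 libraries of a pool. Fst falls from 23.8 CPM in control apex to 9.74 in cKO apex, while Tectb falls from 27.3 to 9.04 in the apex and rises from 0.774 to 3.73 in the middle.

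The control apex and base were compared to describe the difference between these pools along the control cochlea. Tectb, which encodes the tectorial membrane protein beta-tectorin, was the most strongly apical of the named genes at 0.146 ± 0.0962 CPM in the base and 27.3 ± 0.609 in the apex, a log2 change of 7.44 ± 0.14. Fst rose by 3.43 ± 0.085 from base to apex, and Plbd1 rose from 15.3 to 155.5 CPM. In the other direction, Rbp4, which encodes the plasma carrier of retinol, stood at 32.2 CPM in the base and 0.306 in the apex, a log2 change of -6.7 ± 0.12. Other genes higher in the apex by the naming rule were Bpifb3 (5.04), Ppp1r17 (4.22), Ankrd63 (3.6), Apoa4 (3.1), Ppapdc1a (3.01), Zp1 (3) and Lhx1 (2.96). Other genes lower in the apex were Cyp2f2 (-6.43), Slc47a1 (-5.25), Ppbp (-5.19), Penk (-5.1), Hoxa2 (-5.08), Atn1 (-4.42, a symbol on more than 1 row), Bpifa1 (-4.13), Slc6a12 (-3.79) and Prg4 (-3.66), all as log2 changes. Bpifa1 and Cyp2f2, genes of airway epithelium, stood at 110.9 and 12.07 CPM in control base but at 0.543 and 0.1962 in control middle. Tissue from outside the cochlea may thus add to the difference between these pools, which was not tested.

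Hair cell genes were higher in the control apex. Of 26 hair cell genes, 15 were higher in the apex, among them Myo15 (1.74 ± 0.04), Pou4f3 (1.81 ± 0.069) and Chrna10 (2.46 ± 0.069), and 1 was lower, Whrn (-1.16 ± 0.031). The hair cell list had a median of 1.19 (camera adjusted p = 1.88e-12). Of 11 outer hair cell genes 4 were higher, such as Ocm (1.98 ± 0.025) and the motor protein gene Slc26a5 (2.57 ± 0.075), and of 9 inner hair cell genes 4 were higher, such as Otof (1.46 ± 0.027). Their medians were 0.41 (adjusted p = 0.000451) and 0.8 (adjusted p = 7.56e-07). Of 20 supporting cell genes 5 were higher, among them Epyc (1.88 ± 0.0069), Emilin2 (2.63 ± 0.024) and Fgfr3 (1.18 ± 0.03), and the median was 0.42 (adjusted p = 5.44e-06). Neural lists shifted upward with few calls: spiral ganglion neurons had a median of 0.31 (1 of 26 higher, Th at 2.37 ± 0.16, adjusted p = 6.99e-07). Potassium, sodium and pacemaker channels had a median of 0.32 (2 of 22 higher, adjusted p = 1.79e-09), and Schwann cells and peripheral myelin 0.4 (0 of 17 called, adjusted p = 6.43e-15).

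The osteoblast, osteoclast and fibrocyte lists were lower in the control apex than in the base. Of 16 osteoblast and bone matrix genes 11 were lower in the apex, led by Col1a1 (-3.62 ± 0.022), with a median of -1.38 (adjusted p = 1.11e-16). Osteoclast genes had a median of -1.09 (3 of 6 lower, adjusted p = 0.00319). Cartilage genes had 6 of 10 lower and 1, Epyc, higher, and as a list did not pass (adjusted p = 0.11). Fibrocyte and spiral ligament genes had 2 of 12 lower, Otos (-1.24 ± 0.0055) and Dcn (-1.02 ± 0.012), with a median of -0.43 (adjusted p = 1.38e-07). Oligodendrocyte and astrocyte genes had 7 of 15 lower and a median of -1.55 (adjusted p = 0.00721). Melanocytes (-0.38, 2 of 12 lower), stria vascularis marginal cells (-0.2, 0 of 14 called), red blood cells (-0.58, 2 of 13 lower), macrophages (-0.5, 2 of 12 lower) and neutrophils (-0.34, 0 of 15 called) were lower as lists. The interferon response list was higher (0.49, 0 of 14 called, adjusted p = 8.23e-05).

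In the pathways that the series is about, the control gradient was carried by few genes. Of 35 genes of the activin, BMP and follistatin pathway, 4 were higher in the apex: Fst, Inhba (1.5 ± 0.17), Inhbb (1.2 ± 0.2) and Acvr1c (1.82 ± 0.26). Gdf10 was lower (-1.67 ± 0.076), and the list did not pass (median 0.06, adjusted p = 0.792). Of 19 hedgehog pathway genes, the transcription factor genes Gli1 (-1.38 ± 0.086) and Gli2 (-1.21 ± 0.083) were lower in the apex, and the list did not pass (median -0.18, adjusted p = 0.0575). Of 20 developmental gradient and retinoid genes 2 were higher and 2 were lower, A2m (-1.86 ± 0.013) and Cyp26b1 (-1.51 ± 0.088), with no list call (adjusted p = 0.185). The tectorial and acellular membrane matrix list went both ways (4 higher and 2 lower of 12, median -0.15, mean 0.66, adjusted p = 0.252).

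In the control, 981 of 17901 genes were called between apex and base, 408 higher and 573 lower in the apex. Between apex and middle 949 were called (373 higher and 576 lower in the apex). Without the fold threshold both balances turn, with 4786 higher and 4610 lower for apex against base and 4138 and 4001 for apex against middle. Between middle and base 488 were called (273 higher and 215 lower in the middle). The counts adjusted over the list alone were the same for all lists but oligodendrocytes and astrocytes (8 in place of 7). With an estimated correlation, the calls of mitochondrially encoded transcripts (median -0.13, adjusted p = 0.112 with an estimated correlation), proliferation (median -0.48, adjusted p = 0.0654) and endothelium and pericytes (median -0.26, adjusted p = 0.0559) were lost. Of the genes called between control apex and base, 282 remain countable at a mean of at least 5 CPM, a level added after seeing the data.

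The cKO and control apex were compared to see what differs between the genotypes where Fst is most abundant. Xist and Y-linked genes differed too, here and in the other regions, so sex mix cannot be separated from the loss of Fst. Tectb fell with Fst, from 27.3 to 9.04 CPM (log2 change -1.6 ± 0.065, adjusted p = 7.4e-21). Red blood cell genes rose together, and hair cell genes did not pass the test. Among the increases by the naming rule, Bpifa1, a secreted protein of upper airway epithelium, rose from 6.33 to 309 CPM (5.61 ± 0.031), Cyp2f2, a cytochrome P450 of airway secretory cells, from 0.136 to 22.6 CPM (7.34 ± 0.18), and Ppbp, a platelet chemokine gene, from 0.192 to 6.29 CPM (5 ± 0.2). Bpifa1 was also at 110.9 CPM and Cyp2f2 at 12.07 CPM in control base, and Ppbp at 16.7 CPM in control middle.

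Further increases by the rule were Cyp2a5 (6.47), Ccdc108 (5.85), the pseudogene Rps15a-ps7 (5.33) and the axonemal dynein genes Dnah5 (4.18) and Dnah3 (3.55). Rps13-ps1, a pseudogene with 0 counts in the control apex, was at least 87.6-fold higher, and Sec14l3, also at 0 there, at least 77.5-fold higher. The decreases were Mobp, a myelin gene of oligodendrocytes (-3.72 ± 0.2, from 3.92 to 0.294 CPM), Xist, the RNA of X inactivation (-2.16 ± 0.02, from 361 to 81.1 CPM), Slc6a13 (-1.65), Tectb, Mfrp (-1.55), Gfap, an astrocyte filament gene (-1.42), Cdr1 (-1.34), Fst, Rec8 (-1.21) and Pla2g4b (-1.2).

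In the organ of Corti lists of the cKO apex, 0 members were called apart from Tectb. Of 26 hair cell genes 0 were called (median -0.06, camera adjusted p = 0.448), and the same held for the 11 outer hair cell genes (median -0.04, adjusted p = 0.54). Inner hair cell genes were slightly lower as a list (median -0.07, 0 of 9 called, adjusted p = 0.0197), and supporting cell genes slightly higher (median 0.12, 0 of 20 called, adjusted p = 0.00492). Of 12 tectorial and acellular membrane genes Tectb alone was called, and the list did not pass (median 0.07, mean -0.06, adjusted p = 0.152). Of 19 hedgehog pathway genes 0 were called (median 0.06, mean -0.01, adjusted p = 0.558), with Gli1 at -0.03 ± 0.11, Ptch1 at -0.13 ± 0.029 and Shh at 0.25 ± 0.13. Of 35 activin, BMP and follistatin genes only Fst was called (median 0.06, adjusted p = 0.271), and Id1, a target gene of BMP signals, stood at 0.58 ± 0.026. Of 20 developmental gradient and retinoid genes only Tectb was called (median 0.04, mean -0.06, adjusted p = 0.257).

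Neural lists were lower in the cKO apex, each by less than the fold threshold. Spiral ganglion neurons had a median of -0.35 (0 of 26 called, adjusted p = 3.8e-17), and 19 of the 26 were lower by adjusted p alone. Calb2 stood at -0.52 ± 0.0042 and the synaptic gene Snap25 at -0.43 ± 0.0058. Channels had a median of -0.24 (0 of 22 called, adjusted p = 2.09e-12), and Schwann cells and peripheral myelin -0.33 (0 of 17 called, adjusted p = 3.22e-18). Central glia moved in the same direction: of 15 oligodendrocyte and astrocyte genes 5 were lower, with a median of -0.47 (-0.36 with a member at 0 counts set at its bound, adjusted p = 0.0141).

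The red blood cell, neutrophil, proliferation and osteoblast lists rose beside them. All 13 red blood cell genes were higher (median 1.35, adjusted p = 1.29e-16), among them Alas2, the first enzyme of heme synthesis in red cells (1.28 ± 0.044), and Hbb-bs (1.35 ± 0.02). Of 15 neutrophil genes 3 were higher (median 0.83, adjusted p = 2.46e-08), and of 15 proliferation genes 5 (median 0.8, adjusted p = 2.71e-05), among them Mki67 (1.03 ± 0.055; not called without control apex replicate 1, at 0.97, or without cKO apex replicate 2, at 0.99). Of 16 osteoblast and bone matrix genes 2 were higher, Ibsp (1.52 ± 0.045) and Bglap (1.01 ± 0.088), with a median of 0.49 (adjusted p = 3.39e-09). Melanocytes (median 0.18, 1 of 12 higher, Trpm1 at 1.4 ± 0.098) and fibrocytes and spiral ligament (median 0.16, 0 of 12 called) were higher as lists. Clock genes (median 0.31, 0 of 15 called) and mitochondrially encoded transcripts (median 0.11, 0 of 7 called) were as well. Among sex-chromosome transcripts, Xist fell while Eif2s3y (0.88), Ddx3y (0.86), Uty (0.81) and Kdm5d (0.75), all Y-linked, lay higher in the cKO.

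In the apex 365 genes were called, 266 higher and 99 lower in the cKO (3899 and 3367 without the fold threshold). Among genes with a mean of at least 5 CPM, a level added after seeing the data, 49 were called. On the FPKM scale with 1 added, 46 were called. Adjusted over the list alone, the counts were the same for all lists but oligodendrocytes and astrocytes (6 in place of 5) and skeletal muscle (0 in place of 1, Acta1, which was also not called without control apex replicate 1, control apex replicate 3, cKO apex replicate 2 or cKO apex replicate 3, at 1.61, 1.39, 1.58 and 1.4). The call of Reissner's and mesothelial layers (median -0.31, mean 0.26, 1 of 4 higher, Msln at 2.15 ± 0.27) was lost with an estimated correlation (adjusted p = 0.08). The lists of marginal cells, cartilage, B cells, osteoclasts, macrophages, interferon response, endothelium, skeletal muscle, vestibular genes, and immediate early and stress genes did not pass in the apex, and for the first 3 the median and the mean or the test differed in sign.

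**Figure D2:**
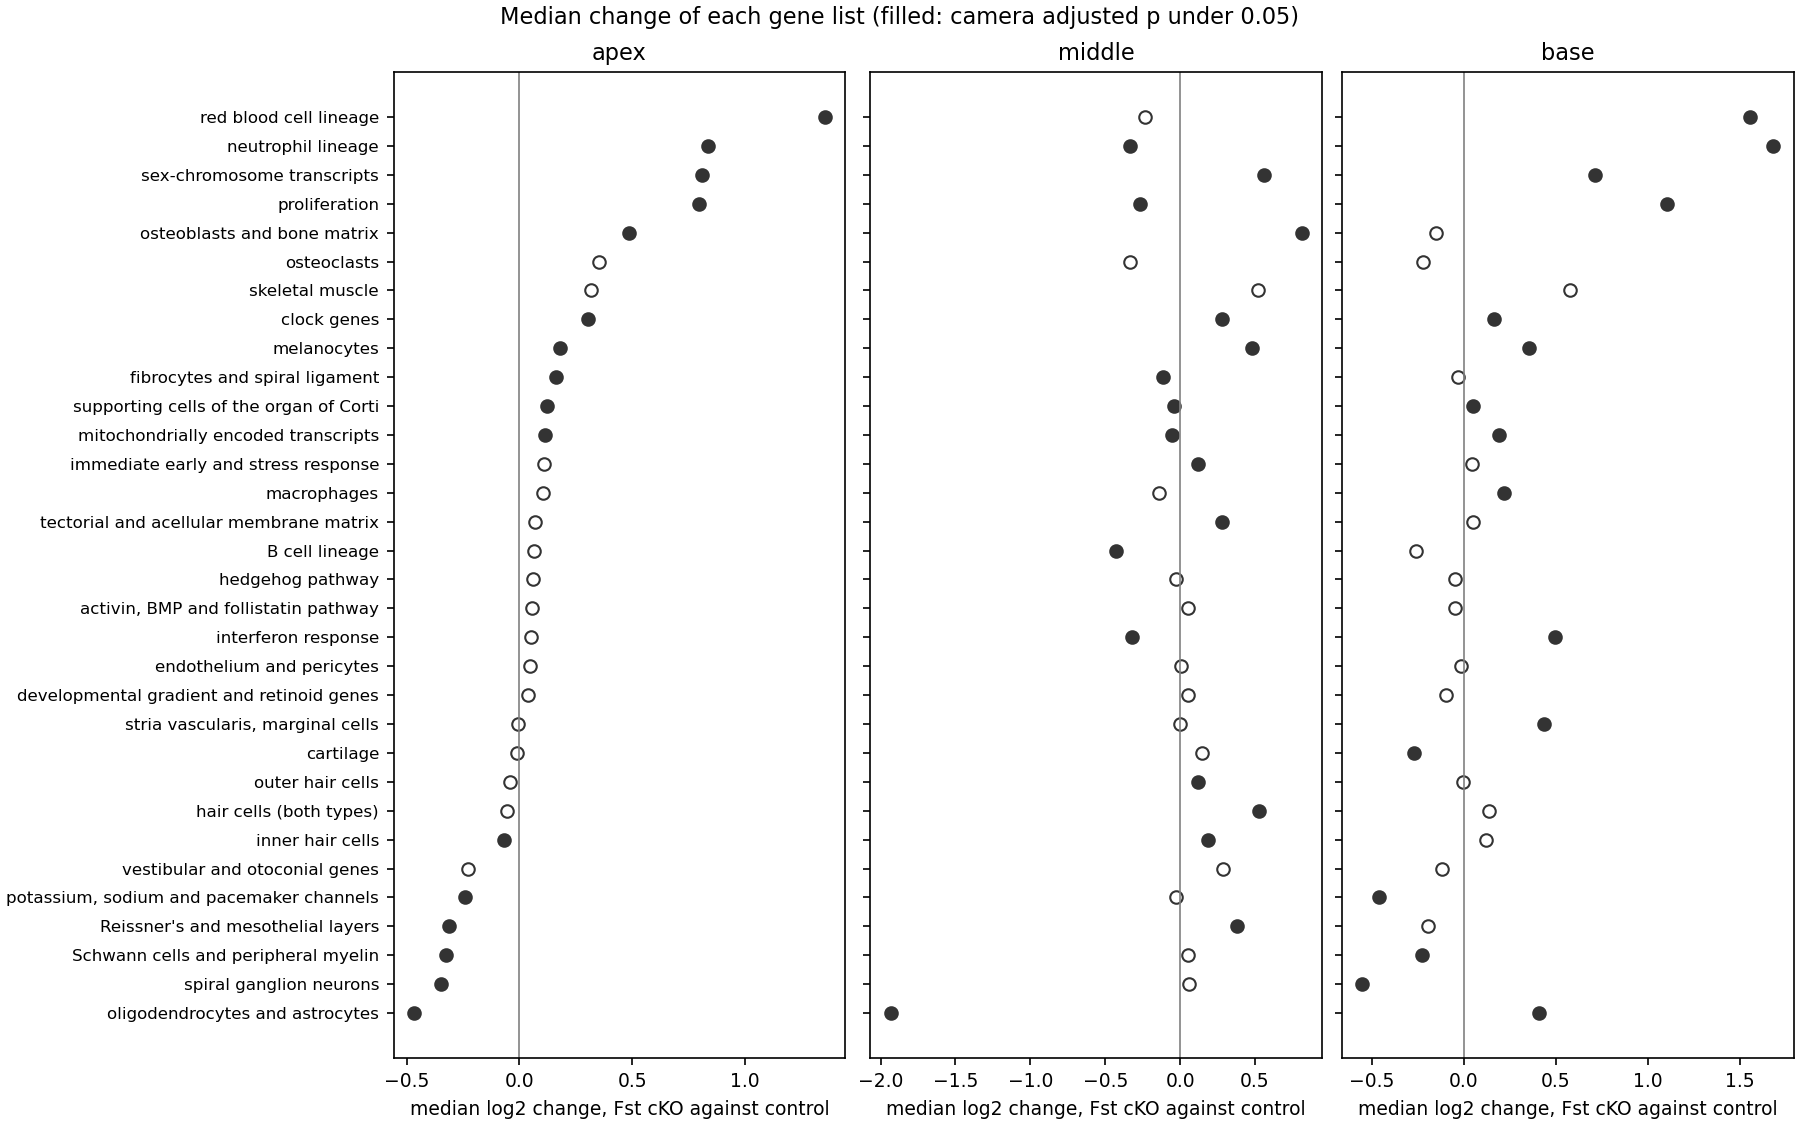
Median log2 change, cKO against control, of the 32 gene lists in apex, middle and base, with filled points for lists with a camera adjusted p under 0.05. The horizontal range differs between panels, with red blood cell genes at 1.35 in the apex, oligodendrocytes and astrocytes at -1.93 in the middle and neutrophil genes at 1.68 in the base.

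In the middle, Fst is expressed at an intermediate level, and the comparison asks whether the genotypes differ there too. Tectb rose in the cKO middle, from 0.774 to 3.73 CPM (log2 change 2.26 ± 0.16, adjusted p = 3.94e-14), opposite to its fall in the apex, and the difference between both effects was 3.86 (adjusted p = 4.66e-20). Tecta, which encodes alpha-tectorin of the same membrane, rose from 1 to 16.7 CPM (4.05 ± 0.11). Hair cell genes rose: of 26, 6 were higher, among them Ptprq (2.51 ± 0.061), Xirp2 (2.89 ± 0.2), Gfi1 (1.01 ± 0.11) and Lhx3 (1.13 ± 0.21), with a median of 0.53 (adjusted p = 2.28e-09). Of the increases by the naming rule, Chrna6, a nicotinic receptor subunit at 14.9 CPM, was at least 429-fold higher, against 0 counts in the control middle, and Onecut1 at least 99.2-fold higher. Skor2, a gene of the second cerebellum list, had 61 counts in the cKO middle and 0 in the control middle. The hair cell and tectorin genes rose in this same pool. Whether their increases come from cochlear cells was not tested.

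Other increases by the rule were Chrnb3, also a nicotinic receptor subunit (8.5 ± 0.2), Hs3st2 (7.86), Fam19a2 (7.46 ± 0.17, from 0.139 to 25.2 CPM) and Ccdc108 (6.27), with Rps13-ps1 at least 88.7-fold higher. With 1 to 3 counts in the control middle, the count ratio was 434 for Rgs8 (95% interval 120 to 3590) and 184 for the neuropeptide gene Tac1 (62.7 to 895). The decreases were Atn1 (-8.18), Sprr1a (-4.9), the oligodendrocyte genes Ermn (-3.54), Mog (-3.12), Olig1 (-3.1), Mobp (-2.84 ± 0.036, from 97.7 to 13.7 CPM) and Hapln2 (-2.34), and Klk6 (-2.69), Bpifb3 (-2.52) and Apoa4 (-2.11). Atn1 is a symbol on more than 1 row, so its change is uncertain.

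Of 12 tectorial and acellular membrane genes 3 were higher in the cKO middle, Tecta, Tectb and Otog (1.24 ± 0.025), with a median of 0.28 (adjusted p = 2.93e-11). Outer hair cell genes (median 0.12, 1 of 11 higher, adjusted p = 0.00032) and inner hair cell genes (median 0.19, 0 of 9 called, adjusted p = 0.00871) were higher as lists, and supporting cell genes lower (median -0.04, 0 of 20 called, adjusted p = 0.00218). Of 19 hedgehog genes 0 were called (median -0.03, mean 0.06, adjusted p = 0.823), with Gli1 at 0.91 ± 0.081. Of 35 activin, BMP and follistatin genes Gdf10 rose (1.06 ± 0.069) and Fst fell, with no list call (median 0.05, adjusted p = 0.0838). Of 20 developmental gradient and retinoid genes Tectb and Calb1 (2.4 ± 0.046) rose, with no list call (median 0.05, adjusted p = 0.823, test direction downward). Spiral ganglion genes had 1 higher, Calb1, and 1 lower, Th (-1.86 ± 0.19), of 26, and did not pass as a list (adjusted p = 0.0885). Kcnd3 (2.75 ± 0.084) and Kcnh7 (1.31 ± 0.049) rose among 22 channel genes, while the list did not pass (median -0.03, mean 0.24, adjusted p = 0.598). Calb1, Kcnd3 and Kcnh7 rose in the pool in which Chrna6 also rose, so their increases need not come from cochlear cells. Schwann cell genes had 1 of 17 higher, Pmp2 (1.18 ± 0.16), and no list call (median 0.05, test direction downward, adjusted p = 0.531).

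Central glia genes were lower in the cKO than in the control middle: 9 of 15 oligodendrocyte and astrocyte genes, with a median of -1.93 (camera adjusted p = 5.72e-17). Mobp stood at 97.65 CPM in control middle, against 21.9 in control base and 3.915 in control apex. In the cKO Mobp stood at 13.67 CPM in middle and 33.27 in base. The control middle was thus the highest pool for Mobp, and whether it held more central tissue was not tested. Bone genes rose, with 5 of 16 higher, among them Col1a1 (1.44 ± 0.024), Ibsp (1.55 ± 0.032), Sost (1.26 ± 0.045) and Bglap (1.37 ± 0.07), and a median of 0.81 (adjusted p = 1.42e-18). Melanocytes (median 0.48, 3 of 12 higher), clock genes (0.28, 0 of 15 called) and the mesothelial list (0.38, 1 of 4 higher) were higher. Fibrocytes (-0.11, 0 of 12 called), neutrophils (-0.33, 0 of 15), B cells (-0.43, 0 of 14), interferon response (-0.32, 0 of 14) and proliferation (-0.27, 0 of 15) were lower. Red blood cell genes did not pass (median -0.24, 0 of 13 called, adjusted p = 0.0673). Xist was lower in the cKO middle (87.1 against 298 CPM), and the Y-linked Eif2s3y (0.83), Ddx3y (0.61), Kdm5d (0.56) and Uty (0.52) lay higher.

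In the middle 487 genes were called, 384 higher and 103 lower in the cKO (3213 and 3172 without the fold threshold). Among genes with a mean of at least 5 CPM, a level added after seeing the data, 86 were called. On the FPKM scale with 1 added, 111 were called. The counts adjusted over the list alone were the same. The calls of immediate early and stress genes (median 0.12, 1 of 18 higher, Fkbp5 at 1.12 ± 0.027; adjusted p = 0.226 with an estimated correlation) and of mitochondrially encoded transcripts (median -0.05, 0 of 7 called; adjusted p = 0.063 with an estimated correlation) were lost. Marginal cells, osteoclasts, cartilage, macrophages, endothelium, skeletal muscle and vestibular genes did not pass as lists, and for marginal cells and endothelium the median and the mean or the test differed in sign.

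In the base, where Fst is lowest, the comparison shows what differs between the genotypes with little Fst present. Red blood cell and neutrophil lists rose: all 15 neutrophil genes and all 13 red blood cell genes were higher in the cKO, with medians of 1.68 (adjusted p = 1.16e-21) and 1.56 (adjusted p = 4.47e-23). S100a9, an abundant neutrophil gene, rose from 28.4 to 98.4 CPM (1.8 ± 0.032) and Alas2 from 20.8 to 71.1 CPM (1.78 ± 0.037). Of the increases by the naming rule, Gabra6, a GABA receptor subunit of cerebellar granule cells, reached 22.2 CPM and was at least 626-fold higher than the control base, at 0 counts, and Neurod1, a neuronal transcription factor gene, rose from 0.188 to 18.2 CPM (6.55 ± 0.17). Col1a1, the main collagen of bone, fell from 526 to 184 CPM (-1.52 ± 0.015).

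Other increases by the rule were Rgs8 (7.57 ± 0.14, from 0.174 to 34.5 CPM), Neurod2 (6.62) and Mybpc3 (6.58). Barhl2 was at least 62.6-fold higher and Rps13-ps1 at least 97.5-fold higher. Slc32a1, the vesicular GABA transporter gene, had a count ratio of 448 (80 to 17700). Other decreases were Xist (-2.37), Slc47a1 (-1.5), Them5 (-1.31), the neuropeptide gene Cartpt (-1.3), Cntnap5c (-1.22), Slc22a6 (-1.16), Rxfp3 (-1.14; not called without cKO base replicate 1, at -0.98), Acp5, an osteoclast phosphatase gene (-1.12), and Adamts12 (-1.08).

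**Figure D3:**
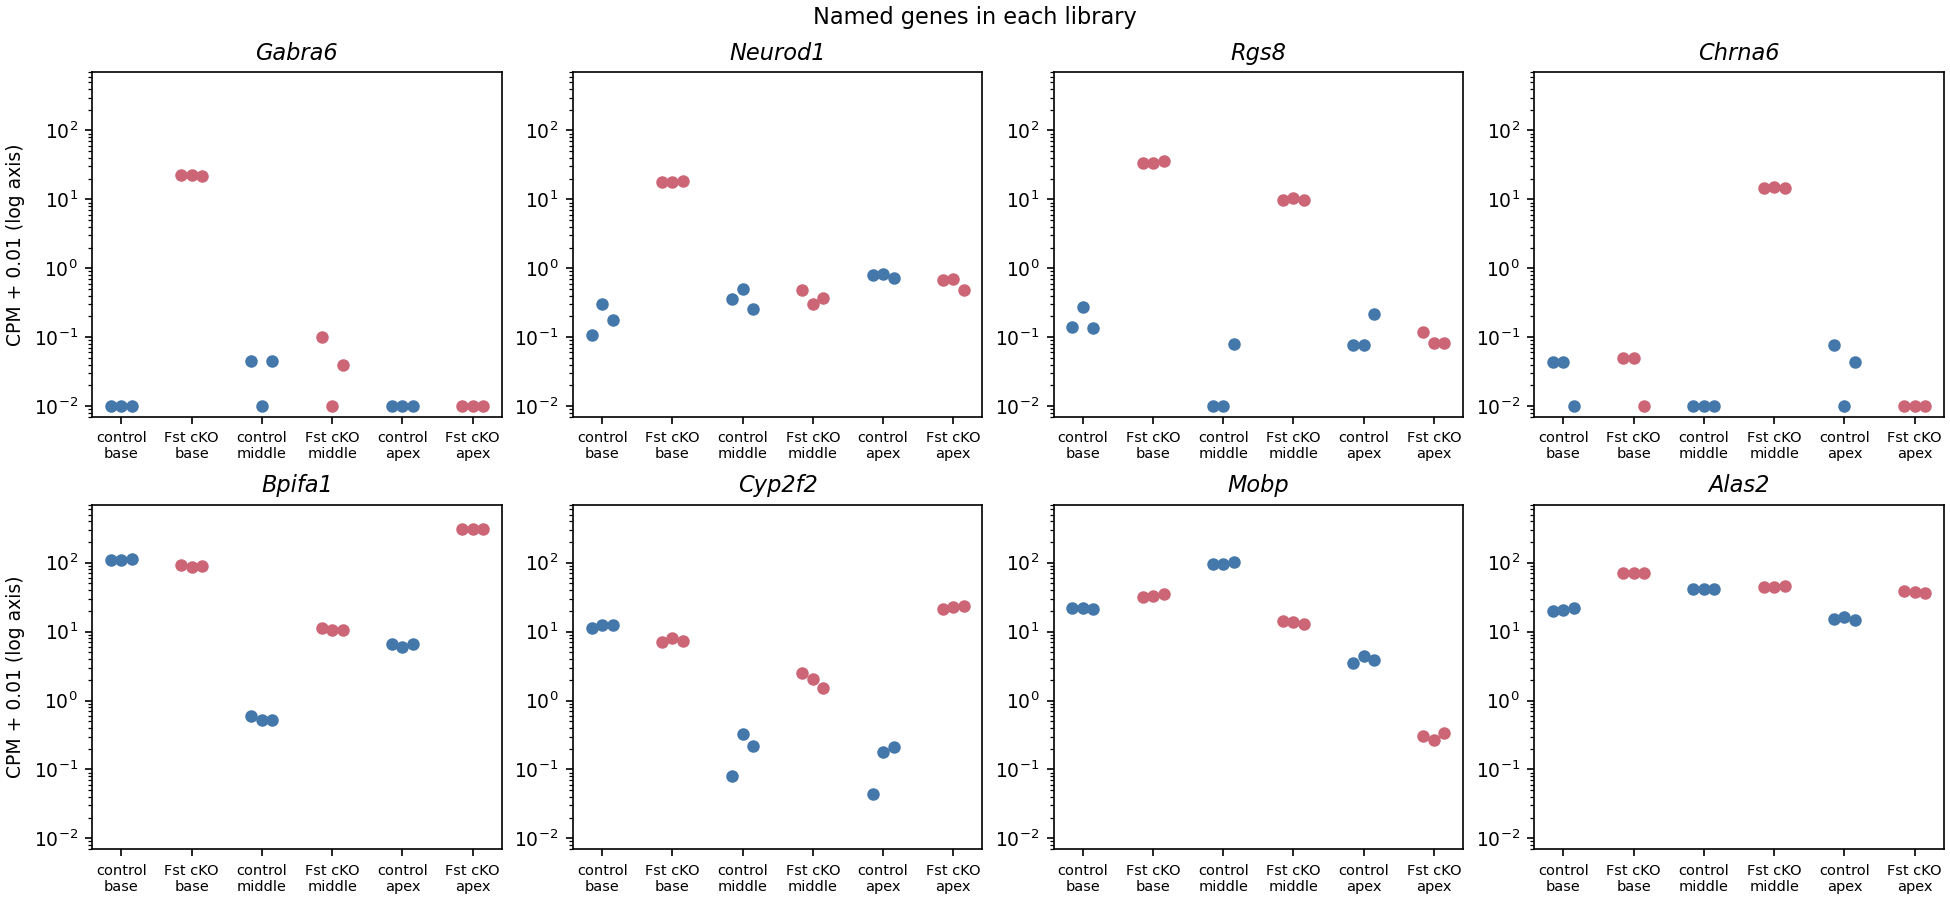
CPM plus 0.01 (log axis) of 8 named genes in the 18 libraries, by region and genotype. Gabra6 reaches 22.2 CPM in the cKO base, Chrna6 14.9 in the cKO middle and Bpifa1 309 in the cKO apex, while the 3 libraries of a pool lie together.

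Spiral ganglion neurons were lower in the cKO base as a list, with a median of -0.55 (adjusted p = 2.61e-20), 1 of 26 called higher, Calb1 (1.89 ± 0.058), and 23 lower by adjusted p alone, such as Nefl, a neurofilament gene (-0.71 ± 0.012), and Calb2 (-0.75 ± 0.013). Channels had a median of -0.46 (adjusted p = 6.53e-09), yet Kcnd2 (2.43 ± 0.13), Kcnd3 (1.6 ± 0.1) and Scn2a1 (1.18 ± 0.057) of the 22 rose. Schwann cells and peripheral myelin had a median of -0.23 (0 of 17 called, adjusted p = 1.88e-12). Hair cell genes had 1 of 26 higher, Barhl1 (1.2 ± 0.26), and did not pass as a list (median 0.14, adjusted p = 0.122). Calb1, Kcnd2, Kcnd3, Scn2a1 and Barhl1 rose in the pool in which Gabra6 and Neurod1 also rose. Their increases need not come from cochlear cells, which was not tested. The lists of outer and inner hair cells, tectorial membrane, hedgehog pathway (0 of 19 called, median -0.05, adjusted p = 0.448) and developmental gradient and retinoid genes (adjusted p = 0.0518) did not pass. Of 35 activin, BMP and follistatin genes Acvr1c rose (1.21 ± 0.29), with no list call (median -0.05, mean 0.03, adjusted p = 0.798). Supporting cells had a median of 0.05 (0 of 20 called, adjusted p = 0.0153).

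Stria vascularis marginal cells were higher (median 0.43, adjusted p = 1.58e-16), as were melanocytes (median 0.35, 1 of 12 called, Tyr at 1.07 ± 0.04). Proliferation genes rose with the red blood cell and neutrophil lists, with 9 of 15 higher and a median of 1.1 (adjusted p = 1.57e-09), and so did the interferon response, with 2 of 14 higher, Ifit3 (1.01 ± 0.035; not called without control base replicate 3, at 0.99, or without cKO base replicate 1, at 1 after rounding) and Rsad2 (1.19 ± 0.07), and a median of 0.5 (adjusted p = 6.36e-09). Oligodendrocytes and astrocytes were higher (median 0.41, 2 of 15 called, Olig1 and Olig2, adjusted p = 0.0271), and the difference between the apex and base effects on this list had a median of -0.91 (adjusted p = 4.27e-06). Of 13 skeletal muscle genes 5 were higher, such as Ryr1 (3.71 ± 0.26), with no list call (median 0.58, adjusted p = 0.0654). Cartilage was lower (median -0.27, 1 of 10 called), and osteoblasts and bone matrix did not pass (median -0.15, 1 of 16 lower). Macrophages (0.22, 0 of 12 called), clock genes (0.17, 0 of 15 called) and mitochondrially encoded transcripts (0.19, 0 of 7 called) were higher. Xist stood at 59.8 CPM in the cKO against 309 in the control. The Y-linked Eif2s3y (1.02), Kdm5d (0.71), Uty (0.71) and Ddx3y (0.68) lay higher in the cKO. Eif2s3y was called, but not in 2 of the fits that each left out a library.

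In the base 542 genes were called, 450 higher and 92 lower in the cKO, a balance that turns without the fold threshold (2945 higher and 3514 lower), and 86 at a mean of at least 5 CPM, a level added after seeing the data. On the FPKM scale with 1 added, 122 were called. The counts adjusted over the list alone were the same, and all list calls in the base held with an estimated correlation. Fibrocytes, mesothelial layers, osteoclasts, B cells, endothelium, vestibular genes, and immediate early and stress genes did not pass as lists. Median and mean or test differed in sign for inner hair cells, fibrocytes, endothelium and vestibular genes.

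Across the regions, the genotype effects on 14049 genes with a mean of at least 2 CPM correlated at r = 0.334 between apex and base, 0.081 between apex and middle and 0.14 between middle and base, across genes, which are not independent replicates. Genes called higher in both regions numbered 82 for apex and base (6.7 if the calls were independent), 57 for apex and middle (5.7) and 75 for middle and base (9.7). Those called lower in both numbered 18, 16 and 12, and those called in opposite directions 11, 28 and 27, in the same order. The regional pools of a genotype may come from the same animals, so the regions need not be independent in these counts or in the next test. When the libraries were summed to 6 pools and region was a factor, edgeR called 0 of 19038 genes for genotype, with 2087 at an unadjusted p under 0.05. DESeq2 called 45 of 28532 genes without the filter on low counts (1589 at an unadjusted p under 0.05), and 41 of the same 19038 genes, a setting added after seeing the data. Both fits take differences between regions in the genotype effect as error, so they are not suited to show an effect in a single region.

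The apex-base change was then compared between the genotypes, to see how far the gradient of the control is kept in the cKO. In the cKO, 1182 genes were called between apex and base, 500 higher and 682 lower in the apex (5467 and 4428 without the fold threshold), and both gradients correlated at r = 0.715 across genes. Of 408 genes higher in the control apex, 248 were also called higher in the cKO apex (11.4 if independent), and of 573 lower genes 276 (21.8 if independent). Fst kept a gradient of 2.36 ± 0.11 in the cKO, against 3.43 ± 0.085 in the control. In the cKO, 12 of 26 hair cell genes (median 0.91, adjusted p = 8.67e-09), 4 of 11 outer and 4 of 9 inner hair cell genes and 5 of 20 supporting cell genes were higher in the apex, and 11 of 15 neutrophil genes (median -1.25, adjusted p = 1.33e-11) and 4 of 13 red blood cell genes (median -0.91) were lower.

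**Figure D4:**
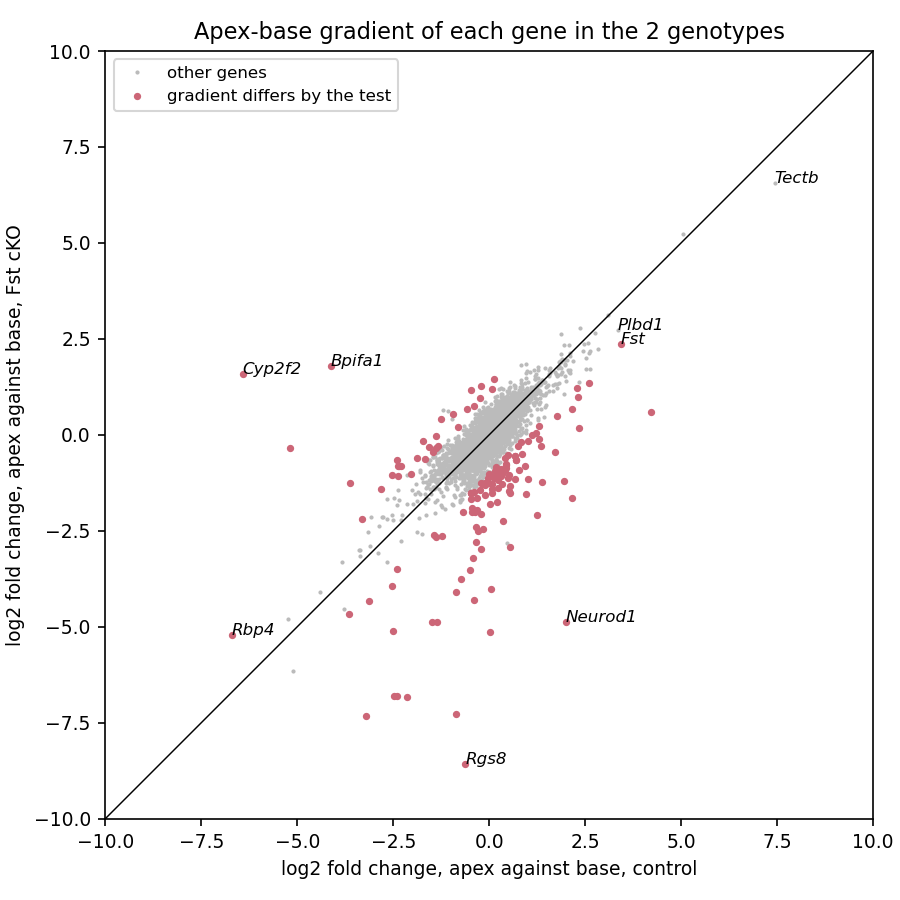
Log2 change from base to apex in the control (horizontal) and in the cKO (vertical) of 14049 genes with a mean of at least 2 CPM, with the 144 genes of called gradient difference marked. The gradients of both genotypes correlate at r = 0.715 across genes.

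The gradient itself differed between the genotypes for 432 genes, with 153 more apical and 279 more basal in the cKO, a balance that turns without the fold threshold (2915 more apical and 1524 more basal). Fst was among them, at -1.07 ± 0.17 (adjusted p = 4.68e-06), as was the activin receptor gene Acvr1c at -1.7 ± 0.36. Tectb was not (-0.87 ± 0.69, adjusted p = 0.431). Its difference is below the fold threshold, and its base counts are near the floor in both genotypes, which makes the value uncertain. Of the genes named above, Cyp2f2 (8.01 ± 0.22) and Bpifa1 (5.91 ± 0.042) were more apical and Neurod1 (-6.88 ± 0.38) more basal. Of 26 hair cell genes, Elmod1 (-1.15 ± 0.12) and Xirp2 (-1.5 ± 0.36) were more basal in the cKO. Of 22 channel genes 3 were, Kcnd2 (-3.34 ± 0.2), Scn2a1 (-1.4 ± 0.087) and Kcnd3 (-1.38 ± 0.16). These 3 rose in the cKO base, where tissue from outside the cochlea stays a possible source. Of 19 hedgehog genes 0 were called (median 0.1, adjusted p = 0.141), with Shh at 0.89 ± 0.18. Of 16 bone genes 5 were more apical, with Col1a1 at 2.37 ± 0.039, and of 15 neutrophil genes 4 more basal (5 adjusted over the list alone). At a mean of at least 5 CPM, a level added after seeing the data, 85 genes were called.

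Genes graded between control middle and base were followed in the apex comparison, which shares no library with them, to ask whether apical character is lost. The 273 genes higher in control middle than base had a median of 0.55 in the cKO apex (limma camera, adjusted p = 0.00051). The 246 of them outside the blood, bone, cartilage and skeletal muscle lists had a median of 0.443 (adjusted p = 0.0284). The 215 genes higher in base had a median of 0.11 (adjusted p = 0.153). The latter passed with an estimated correlation (adjusted p = 0.0267), at 0.431 with lists from control apex against base (adjusted p = 1.98e-07) and at 1.132 with lists at a log2 change of 2 (adjusted p = 2.68e-05), and without cKO apex replicate 1 its median was 0.213, without control apex replicate 1 0.17 and without cKO apex replicate 3 0.179. The genes higher in middle hold genes of blood lineages, such as Alas2 and S100a8, a neutrophil gene. Alas2 stood at 41.5 CPM in control middle against 20.8 in control base, and S100a8 at 41.45 against 14.75. Their log2 changes in the cKO apex were 1.28 ± 0.044 and 0.88 ± 0.045. The sign of the median of the genes higher in middle turns with the gene list. For the 408 genes higher in control apex than base the median was -0.15 (adjusted p = 0.000795), and that list shares the control apex libraries with the comparison.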

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

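Among the tests in this part, those of depth and scaling, of a shifted border and of fewer supporting cells were chosen only after the result was seen, as were the rules on the spread of the values. The 2 second marker lists were written after other genes of the same tissues had been seen, but before their own members were looked at. A first test of depth and scaling was dropped after the values of these lists were seen. A test of a genotype effect in all regions was dropped too, because it ran on genes chosen for the pattern. The neuronal and airway genes were joined into 1 pattern after their values were seen.

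The change from base to apex differed between cKO and control for 432 genes by the interaction test. With the genotype redrawn within apex and base, 5 of 100 drawn splits, the real one included, called at least as many genes, and the highest other count was 473. Chance is therefore not excluded for this count by its splits. The 4 others that reached it keep the base libraries in their genotypes and mix the apex libraries (10 such splits, 236 to 473 genes), and the 79 splits that mix both regions called 0 genes. Counts of that size thus arise when the base libraries alone keep their genotypes. All these splits shuffle technical libraries of single pools, so they cannot test chance between pools or animals.

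For the comparisons of 6 libraries, 1 of the 10 splits, the real one, called as many genes. The 10 splits are too few for a share under 0.05. They also shuffle technical libraries of single pools, so every other split mixes the pools and widens the spread within groups. Few or no calls in the other splits therefore follow from the design. No number of such splits can test chance between pools or animals, so no conclusion on chance is drawn from them. The real counts and the highest counts of other splits were 365 and 0 for cKO against control in the apex, 487 and 0 in the middle, 542 and 0 in the base, 981 and 1 for control apex against base, 949 and 0 for control apex against middle, 488 and 1 for control middle against base, and 1182 and 0 for cKO apex against base. For the 6 summed pools the real split called 0 genes, which 10 of 10 splits reach by construction, so they say nothing of this count. The highest of the other splits called 5.

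Individual genes met the same interaction test, on the log2 scale with positive values more apical in the cKO. Cyp2f2 (8.01), Sec14l3 (7.84), Bpifa1 (5.91), Ppbp (4.85), Ccdc108 (3.92), Dnah5 (3.52), Foxa1 (3.51), Tubb1 (3.31), Dnah3 (3.2) and Upk1b (2.99) were more apical. Barhl2 (-9.71), Rgs8 (-7.96), Neurod1 (-6.88), Mybpc3 (-6.1; not called without control apex replicate 2, at -5.25), Gng13 (-6.05), Neurod2 (-5.89), En2 (-5.72), Pcp2 (-5.6), Acvr1c (-1.7) and Fst (-1.07) were more basal. Barhl2 and Sec14l3 have 0 counts in a group, so their fitted values depend on the prior count and are no bounds. For Tectb, the genotype effect in the middle minus that in the apex was 3.86.

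Gene lists met the interaction test by camera, given here as the median log2 difference of the gradients. More apical in the cKO were osteoclasts (0.696), osteoblasts and bone matrix (0.663), B cells (0.32), cartilage (0.233), spiral ganglion neurons (0.229), channels (0.162), fibrocytes (0.147), developmental gradient and retinoid genes (0.145) and tectorial membrane matrix (0.113). More basal were oligodendrocytes and astrocytes (-0.909, or -0.875 without a member at 0 counts), neutrophils (-0.897), interferon response (-0.421), marginal cells (-0.345), red blood cells (-0.243), hair cells (-0.136), melanocytes (-0.114), mitochondrially encoded transcripts (-0.066) and Schwann cells (-0.054). With an estimated correlation, the calls of tectorial matrix (adjusted p = 0.157), retinoid genes (0.0844), B cells (0.0625), osteoclasts (0.0537) and mitochondrial transcripts (0.0511) were lost. The mean had the other sign for tectorial matrix (-0.09), channels (-0.15) and melanocytes (0.02).

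A first pattern is that genes known from other tissues were higher in the cKO than in the control of a region: Gabra6 and Neurod1 in the base, Chrna6 in the middle, Bpifa1 and Cyp2f2 in the apex, the last pair also at 110.9 and 12.07 CPM in control base and 89.98 and 7.53 CPM in cKO base. Cerebellar tissue in the base pool may be a source: of 12 further cerebellar genes 4 were higher (among them Fat2 at 1.04, Eomes at 3.2 and Skor2 at least 11.8-fold), but the median was 0.29 with the lowest at -0.43. By the rule written before the values were seen, so low a median counts against this source. The rule on spread, chosen after the result was seen, leaves it open, as the SD of the 12 changes was 1.99. Pcp2 (10.45 CPM), En2 (7.568) and Neurod2 (6.236) were also high in the cKO base alone, against at most 0.3578 CPM in any other pool. These genes go with a cerebellar source, but they were picked by the size of their change and are no test of it. Airway or middle ear epithelium in the apex pool stays open by both rules, with 6 of 14 tested genes of a second list higher, among them Reg3g (3.47) and Bpifb1 (2.77), and a median of 0.61. Depth and scaling are argued against, since 2 library totals differed by 1.38-fold at most and the smallest of these 5 changes was 48.8-fold. For an effect of Fst loss in all regions, the 6 summed pools gave 0 of 19038 called genes with edgeR (2087 at an unadjusted p under 0.05) and 45 with DESeq2 (41 of the same genes). The edgeR fit takes differences between regions in the genotype effect as its error, with 2 residual degrees of freedom. It did not call even Xist, at log2 changes of -2.16, -1.77 and -2.37 in apex, middle and base. Its 0 calls are therefore no evidence against such an effect. The pools of a genotype may come from the same animals, so the regions need not be independent there. An effect in a single region stays open, because each pool is single. The reverse, higher in a control pool, was seen for oligodendrocyte genes in the middle, such as Mobp (97.65 CPM in control, 13.67 in cKO). Its source was not tested.

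A second pattern is the lower Tectb in the cKO apex together with its higher level in the cKO middle. The tests here bear on the fall in the apex only. In the middle Tectb rose together with Tecta, Otog and Otol1, the last a member of the vestibular list, which did not pass there. The cause of that rise was not tested. A border drawn farther toward the middle is argued against as the whole cause: it would need 68.9% of middle tissue in the apex pool and would lower the 14 other genes at least 4-fold higher in control apex than middle by a median of -1.11, while they stood at -0.44 (bootstrap interval -0.5 to -0.13) with 0 called lower. That median is not 0, so a smaller shift could still add to the fall. A general loss of supporting cells is argued against by the supporting cell list, with a median of 0.12. The median of a list in whole tissue cannot show whether only the cells that make Tectb were fewer, so that stays open. An effect of Fst loss on Tectb stays open as a hypothesis and cannot be separated here from a difference between single pools.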

How the results depend on the processing

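Counting only genes with a mean of at least 5 CPM, leaving out other-tissue and sex-chromosome lists and DESeq2 on filtered pools were chosen after seeing the data. Counts below are in the order cKO against control in apex, middle and base, control apex against base, apex against middle and middle against base, cKO apex against base, and gradient difference. The p-values carry library spread of single pools, whatever the setting. Depth limits genes near the floor of 3 counts, where fitted folds depend on the prior count.

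Counts moved by construction with the thresholds: without the fold threshold they were 7266, 6385, 6459, 9396, 8139, 5647, 9895 and 4439, and at an absolute log2 change of at least 2, 123, 181, 153, 259, 206, 72, 327 and 192. On log2(FPKM + 1), which shrinks changes of weakly expressed genes, they were 46, 111, 122, 253, 203, 84, 311 and 111. On log2(FPKM + 0.1) the apex (223), middle (323) and control middle against base (301) counts moved by more than 1.5 times. Among genes of at least 5 CPM they were 49, 86, 86, 282, 217, 89, 280 and 85, since fewer genes were counted. Without the other-tissue and sex-chromosome lists they were 334, 465, 496, 941, 894, 438, 1128 and 406. DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, only the groups of the contrast and library sizes without blood lists kept the counts within 1.5 times.

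Leaving out each library gave 360 to 383 genes in the apex, 490 to 510 in the middle, 532 to 585 in the base, 985 to 1014, 943 to 964 and 467 to 489 for the control comparisons, 1181 to 1232 for cKO apex against base and 411 to 433 for the gradient difference.

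The replicate numbers 1 to 3 do not pair the libraries: residuals of libraries with the same number correlated at -0.114 to 0.145 over 21 pairs, and in 4 of 21 the best partner had the same number. With the number as a block, 363 genes were called in the apex, 106 list tests were called, and all 266 results on named genes stayed on the same side of the threshold.

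Fst misses an absolute log2 change of 2 by construction (-1.29 in the apex, -1.1 in the middle), and on log2(FPKM + 1) its middle change was -0.74. Leaving out each library gave -1.32 to -1.26 in the apex, -1.2 to -1.04 in the middle, -0.26 to -0.15 in the base, 3.39 to 3.51 for control apex against base and 2.31 to 2.4 for cKO apex against base.

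For the 6 summed pools, called genes rose from 0 to 45 with DESeq2 and no filter, 41 with DESeq2 on the filtered genes, 6 with edgeR and no filter, 4 without the region factor, 18 without the base pools and 1 without the middle pools, and stayed at 0 without the apex pools, with DESeq2 size factors and without the fold threshold. The cause was not tested.

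Genes higher in control middle than base had a median of 0.545 in the cKO apex, which turned to -0.149 with lists from control apex against base, which share the control apex libraries, and to -0.323 (adjusted p = 0.235) with lists at a log2 change of 2. The cause was not tested. Without the blood, bone, cartilage and skeletal muscle lists the median of 0.545 became 0.443 (246 genes, adjusted p = 0.0284). The oligodendrocyte and astrocyte list was not left out there. Leaving out each library gave 0.502 to 0.553. Genes higher in base (0.112) passed the test at 0.431 with the lists from control apex against base, at 1.132 with lists at a log2 change of 2, and at 0.112 with an estimated correlation (adjusted p = 0.0267). Leaving out each library gave 0.111 to 0.213, the highest without cKO apex replicate 1.

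Of 192 list tests, 106 were called, 95 with an estimated correlation, 181 with fry and 111 on log2(FPKM + 0.1), 101 of them shared. Fry tests another question, since it compares a list with no other genes.

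Of 266 results on named genes, 266 stayed on their side with DESeq2 size factors, 265 with the DESeq2 Wald test, 265 without a filter, 239 on log2(FPKM + 0.1), 180 on log2(FPKM + 1) and 135 at a log2 change of 2. Leaving out libraries kept 1798 results and weakened 26. The called gradient difference of Mylpf, a muscle gene (-1.29), turned to 0.07 on log2(FPKM + 0.1) and 0.05 on log2(FPKM + 1), and the cause was not tested. Its call was also lost without control apex replicate 1 (-0.96), cKO base replicate 2 (-1.12) or cKO apex replicate 1 (-1.17).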

Other observations

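The tests of sex mix, strain background and time of day, the count of genes changed alike and the comparison of gradient sizes were chosen only after the result was seen.

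A group of genes changed alike in all 3 regions. The regions share no library, but the regional pools of a genotype may come from the same animals, so the regions need not be independent. At an absolute log2 change of at least 0.5 with an adjusted p under 0.05, 55 genes were higher and 32 lower in the cKO in all 3 regions, against 1.46 and 0.227 if the regions were independent. At the threshold of 1 used elsewhere, 16 were higher and 8 lower (0.143 and 0.00293 if independent). Without a fold threshold 519 were higher and 639 lower (115 and 117 if independent). Fkbp5, a chaperone gene that responds to glucocorticoids, stood at 1.05 ± 0.032 in the apex, 1.12 ± 0.027 in the middle and 0.83 ± 0.028 in the base. The clock gene Per2 stood at 0.85 ± 0.029, 0.9 ± 0.029 and 0.82 ± 0.03, and Dbp, a gene under clock control, at 0.73, 0.94 and 0.62. Calb2, a calcium-binding protein gene of neurons, stood at -0.52 ± 0.0042, -0.69 ± 0.0061 and -0.75 ± 0.013, and Ttn, the gene of titin, at -0.59, -1.12 and -1.04. Gas5, a non-coding RNA gene, stood at -1.15, -0.91 and -0.8. Of the clock genes, the activators Arntl (-0.41 ± 0.057 in the apex) and Npas2 (-0.49 ± 0.064) lay lower while Per2 and Dbp lay higher.

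Otol1 and Oc90 are on the list of vestibular genes, which did not pass in apex, middle or base. Otol1, which encodes a protein of otoconia and tectorial structures, rose in the cKO middle (3.03 ± 0.19) and base (1.19 ± 0.3; not called without cKO base replicate 2, at 0.97) and stood at -0.68 ± 0.18 in the apex. Oc90, the main otoconial protein gene, rose in the base (1.22 ± 0.37; not called without control base replicate 1, at 1.02, or without cKO base replicate 3, at 1 with an adjusted p above 0.05). Calb1, a calcium-binding protein gene, rose in the cKO middle (2.4 ± 0.046) and base (1.89 ± 0.058) and stood at 0.2 ± 0.058 in the apex.

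The last pattern weighed is this group of 87 genes that changed alike. A different sex mix of the pools may account for the X- and Y-linked genes, as 4 X-linked genes outside the group that are known to escape X inactivation (Kdm6a, Kdm5c, Eif2s3x, Ddx3x) were lower by adjusted p in 12 of 12 changes (-0.29 to -0.08), and no test here bears on the others, since a sex mix could also change autosomal genes (9 of 87 lie on X or Y). A different strain background is consistent with the excess of pseudogenes, 14 of 87, with an odds ratio of 8.92 (95% interval 4.6 to 16.1, Fisher's exact p = 5.32e-09). A different time of day at collection is consistent with the 12 clock genes of the list outside the group: with Arntl, Npas2 and Clock against the others, 34 of 36 changes had the sign it needs and 32 of these an adjusted p under 0.05, with Cry1 as the gene that passed in no region and none past the fold threshold. Xist fell in apex, middle and base (log2 changes of -2.16, -1.77 and -2.37) while the Y-linked Eif2s3y, Ddx3y, Uty and Kdm5d lay higher in all 3 regions. That is what a larger share of males in the cKO pools would give. Sex mix therefore cannot be separated from genotype in any genotype comparison here. For the other genes an effect of the genotype itself is not excluded. With 1 pool per group, sex mix, strain background and time of day cannot be told from it for these other genes.

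The control and cKO gradients can also be compared for size. Among the 408 genes higher in control apex the median log2 change was 1.48 in the control and 1.21 in the cKO, and 58 had a called smaller gradient in the cKO against 1 larger. Among the 573 lower genes the medians were -1.49 and -0.99, with 81 smaller and 27 larger. These genes were picked on the control libraries, which by itself favours a smaller value in the cKO. Over 14049 genes the control apex-base change correlated with the change in the cKO apex at r = -0.348 across genes (covariance -0.0402). Both share the control apex libraries. Data simulated with library spread only, and no difference between regions, genotypes or pools, gave r = -0.487 (covariance -0.0019). That r comes from library noise alone and is no measure for the observed r. By covariance, shared library noise was small beside the observed value, while the spread of the shared control apex pool was not simulated. The control middle-base change, which shares none, correlated at r = -0.093 (covariance -0.0067, Spearman rho -0.21) with the change in the cKO apex, where the simulated data gave r = 0.007 (covariance 0).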
